A study of Homo sapiens with 28 samples.

How the data were processed

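RNA from 28 cultures or RNA samples of H9 cells, an established human embryonic stem cell line, was read on single-colour Agilent arrays after labelling with Cy3. The labels give 15 groups: 2 arrays of cells before the time course, and cells kept at 1%, 5% or 21% O2 for 12 h, 24 h, 5 d or 10 d, with 15 d at 5% and 21% O2 as well. Of these groups 13 hold 2 arrays, and 10 d at 1% and at 21% O2 hold 1 array each. The labels do not say whether replicate arrays came from separate cultures or from 1 RNA, so the p-values measure the spread between these arrays, which may in part be technical.

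The deposited scanner tables hold the fluorescence intensity of each spot in arbitrary units, and per the file headers they were made by Feature Extraction 9.5.1.1 with a probe layout drawn up on build hg17. The processed signal in them is already corrected for background by that program. The deposited series matrix holds log2 values for 40736 probes, for which the submitters' processing notes name R 2.5.1 and limma without giving steps. Its columns have medians between 7.816 and 7.903, are not centred by gene, and correlate with the log2 scanner signal across probes at r between 0.977 and 0.995, so a higher value means more signal in both. The scanner tables were used for all results and the series matrix for an alternative.

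On each array, spots that the program marked as non-uniform or as outliers among the spots of a probe were left out. Apart from control spots, which were left out as well, the arrays held 43376 spots of 41000 probes, marked spots included. Of these probes 264 had 10 spots each, which were averaged, and 40736 had 1 spot. Each log2 signal was taken relative to the 75th percentile of its array, so a difference is relative to the bulk of the transcripts on an array. No genome came with the series, and positions on a chromosome were not used. Probe names were brought up to date with the gene tables of GRCh38.p14: 23434 probes were matched by accession, 2317 by symbol and 1043 by an older synonym, and 14206 kept the name in the file. The brightest probe stood for each of 30990 genes. A gene was tested if its probe was well above background on both arrays of at least 1 group of 2 arrays. This kept 24284 genes, 15301 of them with an official symbol and 7088 with several probes. A missing value on at least 1 array affected 379 of the tested genes.

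Comparisons were made with limma 3.58.1 in R 4.3.3, with data.table (version 1.17.8) for reading. One model with 15 group means was fitted to all 28 arrays, which left 13 residual degrees of freedom and a prior of 2.61. A gene was called when its Benjamini-Hochberg adjusted p was below 0.05. The oxygen levels were compared over the mean of 12 h, 24 h and 5 d, where all 3 levels have 2 arrays, and at each time. Late (10 d and 15 d) was compared with early (12 h and 24 h) at 5% and at 21% O2, and 3 tests asked whether an effect differed between times or oxygen levels. Groups with 1 array borrow the spread of the others. Replicate numbers did not pair the arrays, since the replicate differences of 2 groups correlated across genes at r over 0.1 in 18 of 78 pairs of groups, with values from -0.381 to 0.438. Values of groups are means ± SD of the log2 signal relative to the 75th percentile, and differences are log2 ± the standard error of the fit.

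The comparisons, the 23 gene lists, the rule for the genes named and most alternatives were fixed before the data were examined. The lists cover HIF target genes, HIF pathway components, glycolysis enzymes, subunits of the respiratory chain, pluripotency, mesendoderm, endoderm, mesoderm, endothelial, cardiac and smooth muscle, neuroectoderm, neural crest, trophoblast, epidermal and fibroblast markers, cell cycle, p53 target, stress, cholesterol synthesis, immediate early, metallothionein, TGF beta and Wnt genes. They were tested with limma's camera at the preset correlation of 0.01 and again with an estimated correlation, adjusted over the 23 lists and 5 main comparisons together. The rule named, in each main comparison, the 8 largest rises and the 8 largest falls among called genes with an official symbol whose difference had the same sign at every time (for late against early, with no overlap of the late and early arrays), up to 4 called members of each list with the largest difference, and VEGFA, CA9, HIF1A, EPAS1, POU5F1, NANOG, SOX2, PECAM1, CDH5 and KDR where measured. Every other comparison named the 3 largest rises and 3 largest falls. Genes on the Y chromosome, XIST, and names of loci, open reading frames or clones were passed over. Where a gene was not well above background on any array of one side, its fold is given as a lower bound: the mean of the other side against a mean in which each array without clear signal stands at the lowest value well above background on that array, or at its own value if higher. Where it was on some arrays of a side, their number is given, and the fitted difference then rests in part on dim spots, as can the median of a list. The 3 tests of whether an effect differed have no such bound and give the fitted difference even for genes without clear signal at an O2 level.

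The model was tested on simulated data for 23905 genes without missing values, in which 200 genes were changed. The simulated spread was that of the real arrays without 1 array of low signal. The model recovered between 91% and 98% of changes of 2 on the log2 scale and between 64% and 79% of changes of 1. There were between 8 and 15 false calls per comparison. The reported fit keeps the array of low signal, which enters the spread, so these shares need not hold for it.

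Alternatives were quantile normalization, background correction by normexp with an offset of 50 together with quantile normalization, the series matrix, no filter on dim probes, the mean of all probes of a gene, slide as a fixed or a random block, replicate number as a block, only the arrays of the groups compared, and leaving out each array of the groups compared. After the data were seen, 4 alternatives were added. Of these, 2 left out an array of low signal in every comparison, without and with slide as a block. The others were scan day as a block and counting the closely similar 10 d 5% O2 arrays as 1 sample. For a time the model with that pair as 1 of 27 samples was used in place of the one planned. Both had been run and seen when the planned model with 28 arrays was restored, and counts of both are given for the 5 main comparisons and where they differed by over 1.5 times. Positions of spots on the arrays and the red channel, which these arrays lack, were not used.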

Results

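The arrays measured transcripts of H9 cells, a human embryonic stem cell line, grown on extracellular matrix left by foreskin fibroblasts in medium conditioned by such fibroblasts. The title of the series concerns differentiation of these cells under hypoxia. There were 2 arrays of cells at 0 h, which were at 21% O2, and 2 arrays each for 12 h, 24 h and 5 d at 1%, 5% and 21% O2. At 10 d there was 1 array at 1% O2, 1 at 21% O2 and 2 at 5% O2, and at 15 d there were 2 arrays at 5% and 2 at 21% O2. The 75th percentile of the signal lay between 977.9 and 2366 on 27 arrays, which had 63.3% to 79.4% of probes well above background. Replicate 2 of 5 d at 5% O2 had a 75th percentile of 71.63 and 52.2% of probes well above background, and its spike-in level minus its 75th percentile was 8.75 on the log2 scale against 2.54 to 4.28 on the other arrays. It is called the low-signal array. Its highest correlation with any array was 0.683, while the other arrays had median correlations from 0.912 to 0.962 across genes, which are not independent. The pair of 10 d arrays at 5% O2 differed by a median of 0.037 on the log2 scale at probes with several spots, less than the 0.054 between spots of one array. They were therefore counted as 1 sample wherever a mean ± SD is given, and each count of genes was also made with them as 1 sample. The number of arrays limits the precision of every value.

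**Figure D1:**
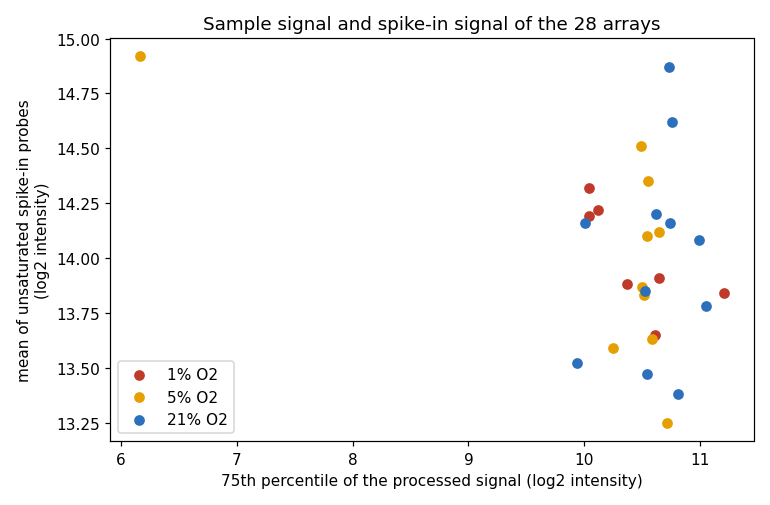
Each point is 1 of the 28 arrays, coloured by O2 level, with the log2 75th percentile of its signal on the x axis and the mean log2 intensity of 7 unsaturated spike-in probes on the y axis. The low-signal array stands alone at the left, while the spike-in level of the others spans 13.25 to 14.87.

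The comparison of 1% with 21% O2, averaged over 12 h, 24 h and 5 d with 6 arrays on each side, asked how strong hypoxia changed the transcripts. All 36 measured HIF target genes, which the hypoxia-inducible factors switch on, rose at 1% O2, with a median log2 difference of 2.68, and 36 did so adjusted over the list alone. NDRG1 (gene ID 10397), a hypoxia-induced gene, rose by 4.45 ± 0.35, ANKRD37 by 4.58 ± 0.23, the carbonic anhydrase gene CA9 (gene ID 768) by 4.15 ± 0.19 and the blood vessel growth factor gene VEGFA by 3.03 ± 0.38, each higher on 6 of 6 arrays than on any array at 21% O2. CA9 was well above background on 5 of 6 arrays at 21% O2. Cytokine genes were among the largest rises: CSF2 (gene ID 1437), which encodes GM-CSF, rose by 6.74 ± 0.56 (5 of 6 arrays at 21% O2 well above background), IL6 by 5.66 ± 0.33 and the neutrophil attractant gene CXCL8 by 5.43 ± 0.55. CSF3, which encodes G-CSF, was at least 34.7-fold higher and LEP, which encodes leptin, at least 11.4-fold higher, since neither was well above background on any of the 6 arrays at 21% O2. COXFA4L3 rose by 4.64 ± 0.26, and STC1, which encodes the hormone stanniocalcin, by 4.50 ± 0.28 (5 of 6 arrays at 21% O2 well above background). The limma adjusted p of these genes lay between 3.66e-09 for CA9 and 1.74e-05 for VEGFA. The HIF target list was called by camera (adjusted p = 1.56e-32), with an adjusted p = 0.0565 with an estimated correlation, or 0.00383 with an estimated correlation when the low-signal array was left out.

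Of 19 glycolysis enzymes 11 rose and 0 fell at 1% O2 (12 adjusted over the list alone, median 0.96), among them ALDOC by 2.44 ± 0.13, the hexokinase gene HK2 by 2.11 ± 0.15 and the lactate dehydrogenase gene LDHA by 1.85 ± 0.29. Of 22 cholesterol synthesis genes 16 rose (16 adjusted over the list alone, where 1 also fell, median 0.79), led by the sterol oxidase gene MSMO1 at 3.11 ± 0.27 and the sterol sensor gene INSIG1 at 2.98 ± 0.15. Of 10 metallothionein genes, which encode metal-binding proteins, 8 rose (9 adjusted over the list alone, median 1.60), with MT1X at 1.96 ± 0.13. Most of these genes were lower at 12 h in 21% O2 than at 0 h, so part of the difference was a fall at 21% O2. Of 23 fibroblast and matrix markers 17 rose (18 adjusted over the list alone, median 1.29), with the matrix protease genes MMP1 at 2.17 ± 0.22 and MMP2 at 2.13 ± 0.29. Of 23 unfolded protein and amino acid stress genes 9 rose and 1 fell (median 0.55), with STC2 at 3.00 ± 0.16 and DDIT3, a stress-induced transcription factor gene, at 1.92 ± 0.17. The camera adjusted p was 1.62e-06 for glycolysis, 1.99e-07 for cholesterol synthesis, 7.02e-09 for metallothioneins, 7.40e-09 for fibroblast markers and 0.00246 for stress genes. With an estimated correlation none of these calls held, with adjusted p = 0.146, adjusted p = 0.179, adjusted p = 0.146, adjusted p = 0.166 and adjusted p = 0.297 in that order. The TGF beta list had 9 of 24 members higher, such as INHBA at 2.23 ± 0.13, and 5 lower (median 0.42, adjusted p = 0.163). Of 21 p53 target genes 6 rose, such as the stress cytokine gene GDF15 at 2.23 ± 0.24, and 1 fell (median 0.19, adjusted p = 0.108). Of 20 immediate early and heat shock genes 6 rose, such as IER3 at 3.80 ± 0.22, and 2 fell, with a median of -0.13, a mean of 0.38 and an adjusted p = 0.405. The list of 14 HIF pathway components had 2 members higher, the coactivator gene CREBBP at 1.11 ± 0.15 and CITED2 at 0.55 ± 0.16, and 2 lower (median 0.03, adjusted p = 0.745). HIF1A differed by -0.31 ± 0.36 and EPAS1 by 0.04 ± 0.46, and neither passed the test. HIF1A passed without the low-signal array (adjusted p = 0.0425).

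Of 34 cell cycle genes 19 fell and 0 rose at 1% O2 (19 adjusted over the list alone, median -0.70), among them the proliferation marker gene MKI67 at -1.27 ± 0.35 and PCNA, the clamp of DNA replication, at -1.59 ± 0.44. Of 22 neuroectoderm markers 9 fell and 1 rose (median -0.97), with the forebrain and eye regulator gene LHX2 at -2.41 ± 0.28. The eye field gene RAX fell by 3.06 ± 0.39, and CYREN, which encodes a regulator of DNA repair, by 2.96 ± 0.20. Of 22 Wnt pathway genes 7 fell and 2 rose (median -0.57), with the receptor gene FZD8 at -2.28 ± 0.13 and AXIN2 at -1.44 ± 0.30. Of 28 pluripotency markers 8 fell and 1 rose (9 and 1 adjusted over the list alone, median -0.38), with ZFP42 at -1.37 ± 0.14 and the Nodal inhibitor gene LEFTY2 at 1.66 ± 0.27, while POU5F1 differed by 0.04 ± 0.20, NANOG by -0.01 ± 0.29 and SOX2 by -0.62 ± 0.25, none past the test. SOX2 passed without the low-signal array (adjusted p = 5.76e-05). The effect on LEFTY2 was more positive by 5.61 at 5 d than at 12 h, so its mean over times rests mainly on 5 d. The camera adjusted p was 1.68e-06 for cell cycle, 0.000549 for neuroectoderm, 0.0221 for Wnt and 0.0284 for pluripotency genes, and no call held with an estimated correlation (adjusted p = 0.244, adjusted p = 0.146, adjusted p = 0.388 and adjusted p = 0.458). MYF6 fell by 3.48 ± 0.18 and PRDM12 by 3.10 ± 0.29, with 1 of 6 arrays at 1% O2 well above background for each.

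Lists of other cell types moved both ways at 1% O2 and were not called by camera. Members that rose and fell numbered 1 and 3 of 15 mesendoderm markers (median -0.28, adjusted p = 0.162), 2 and 4 of 21 endoderm markers (median -1.01, adjusted p = 0.13), 4 and 6 of 20 mesoderm markers (median -0.45, adjusted p = 0.828) and 2 and 4 of 12 neural crest markers (median -0.25, adjusted p = 0.316). They numbered 3 and 5 of 21 endothelial markers (median -0.32, adjusted p = 0.637), 4 and 1 of 18 cardiac and smooth muscle markers (median 0.21, adjusted p = 0.0788), 2 and 6 of 21 trophoblast markers (median -0.30, adjusted p = 0.541) and 2 and 1 of 13 epidermal markers (median 0.16, adjusted p = 0.372). In the mesoderm list TWIST1 rose by 2.13 ± 0.14 and MSX2 fell by 2.13 ± 0.12. Among endothelial markers the VEGF receptor gene FLT1 rose by 1.32 ± 0.17 and ANGPT2 fell by 2.44 ± 0.30, while KDR differed by -0.58 ± 0.22 and did not pass except without the low-signal array (adjusted p = 0.0187), and neither PECAM1 nor CDH5 was among the genes tested. Of 50 respiratory chain and ATP synthase subunits 1 fell, SDHC at -0.79 ± 0.22, and 0 did when adjusted over the list alone (median -0.18, adjusted p = 0.181).

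In this comparison limma called 7466 of 24280 genes, 3390 higher and 4076 lower at 1% O2, and 3738 of them changed at least 2-fold. Without the low-signal array, which is on neither side but enters the spread, 12644 genes were called. With slide as a fixed block the count was 4483, or 10593 with both changes, and with only the arrays of both O2 levels it was 11324. On the slides that held both O2 levels the median of the HIF target list was 2.66 and 2.47 at 12 h and 2.38 at 10 d, that of the fibroblast list 0.97, 0.77 and 1.85, and that of the cell cycle list -0.52, -0.30 and -0.94. The within-slide medians were 1.03, 1.25 and 0.72 for glycolysis, 0.87, 1.1 and 1.85 for cholesterol synthesis, 1.98, 2.02 and 0.60 for metallothioneins, -0.62, -0.23 and -2.22 for neuroectoderm -0.22, -0.19 and -0.02 for pluripotency, 0.30, 0.19 and 0.52 for stress and -0.41, -0.14 and -0.96 for Wnt genes.

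**Figure D2:**
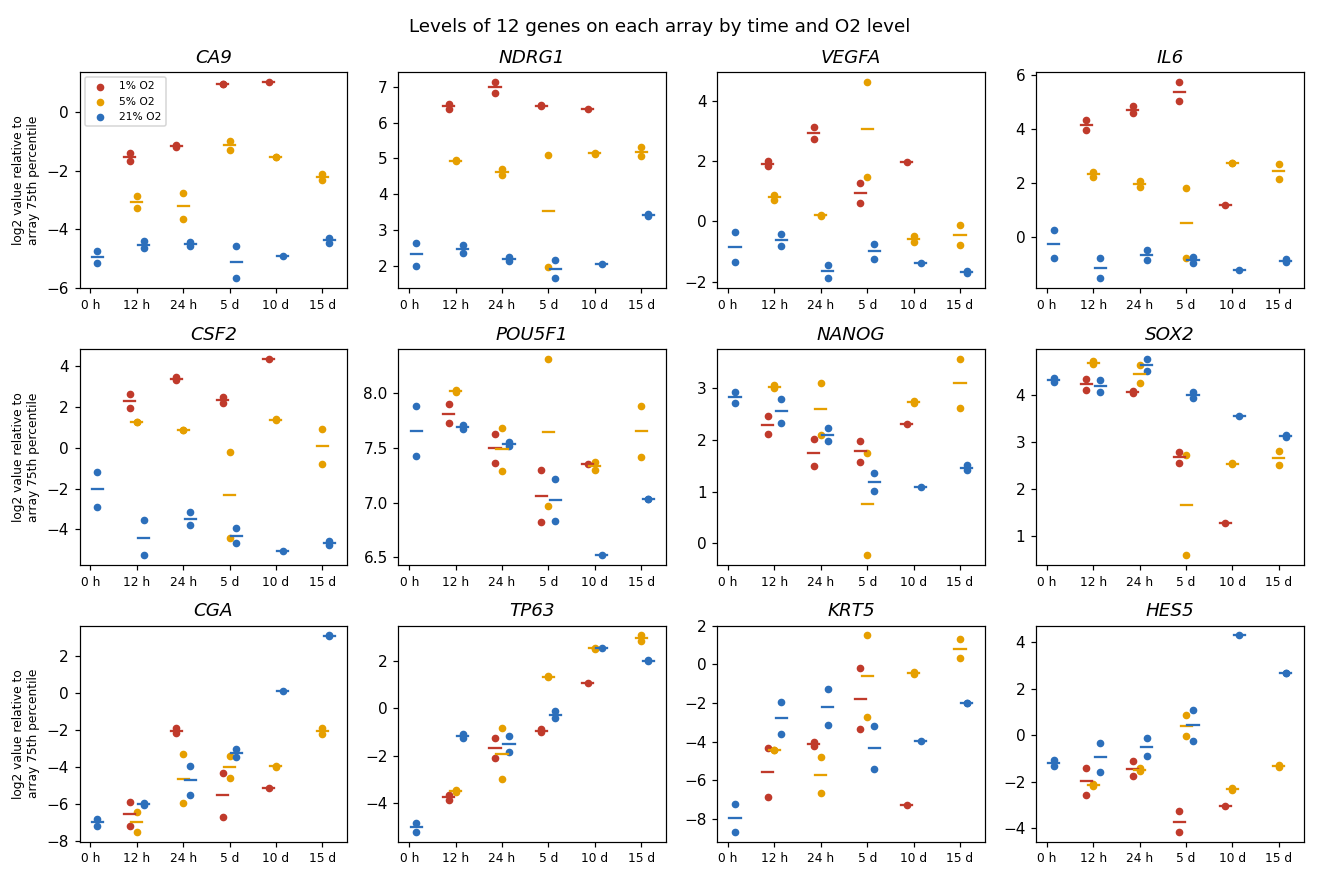
Points show the log2 signal of 12 genes relative to the array's 75th percentile on each array, by time on the x axis and O2 level by colour, with short lines at group means. CSF2 had a mean of 2.31 at 12 h in 1% O2 and -4.41 in 21% O2.

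At 5% against 21% O2, again over 12 h, 24 h and 5 d with 6 arrays a side, 27 of 36 HIF target genes rose and 0 fell, with a median of 1.29, and 30 rose adjusted over the list alone. VEGFA rose by 2.45 ± 0.38 and ANGPTL4, a regulator of lipid breakdown, by 2.23 ± 0.26. CA9 rose by 2.25 ± 0.19 (5 of 6 arrays at 21% O2 well above background). Each was higher on 6 of 6 arrays. At 5 d in 5% O2 VEGFA was at 4.65 on the low-signal array and 1.491 on the other array, so the low-signal array raised its difference. CSF2 rose by 4.0 ± 0.56 (limma adjusted p = 0.000222) and CXCL8 by 2.91 ± 0.55, each higher on 5 of 6 arrays than on any array at 21% O2, and each well above background on 5 of 6 arrays at 5% O2. CSF3 was at least 6.15-fold higher, LEP at least 2.82-fold and IL1RN, which encodes a blocker of interleukin 1, at least 3.12-fold higher. Of 10 metallothionein genes 7 rose (8 adjusted over the list alone, median 0.80), with MT2A at 1.00 ± 0.12. As for 1% O2, the fall of this list at 21% O2 by 12 h makes up part of the difference. Of 19 glycolysis enzymes 5 rose (6 adjusted over the list alone, median 0.30), with HK2 and ALDOC at 1.31 each (SE 0.15 and 0.13), and 4 of 22 cholesterol synthesis genes rose (median 0.18), with INSIG1 at 1.44 ± 0.15. Of 23 fibroblast and matrix markers 4 rose (median 0.15), with MMP1 at 1.71 ± 0.22, and 10 rose (median 0.48) without the low-signal array. TAF9B rose by 2.66 ± 0.26, but 1 other probe of this gene moved in the opposite direction and passed the test.

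Of 22 neuroectoderm markers 7 fell and 0 rose at 5% against 21% O2 (median -0.49), with PAX3, an early neural tube and crest regulator gene, at -2.16 ± 0.32. The teneurin gene TENM4 fell by 2.5 ± 0.30 (2 of 6 arrays at 5% O2 well above background) and the cadherin gene CDH6 by 2.43 ± 0.37. PAX3, CDH6 and PCNA were each well above background on 5 of 6 arrays at 5% O2, and PAX3, TENM4 and CDH6 were lower on 6 of 6 arrays. Of 22 Wnt pathway genes 7 fell (median -0.58), with the Wnt inhibitor gene APCDD1 at -1.58 ± 0.28, and of 34 cell cycle genes 9 fell (12 adjusted over the list alone, median -0.46), with PCNA at -1.67 ± 0.44, or -0.97 without the low-signal array. Of 12 neural crest markers 3 fell (median -0.36), of 21 endoderm markers 2 fell (median -0.99) and of 50 respiratory chain subunits 3 fell, but 0 adjusted over the list alone (median -0.33). Pluripotency markers went both ways, with 2 of 28 higher and 4 lower (median -0.10, camera adjusted p = 0.59). POU5F1 differed by 0.30 ± 0.20, NANOG by 0.18 ± 0.29, SOX2 by -0.68 ± 0.25, HIF1A by -0.50 ± 0.36, EPAS1 by -0.92 ± 0.46 and KDR by -0.28 ± 0.22, none past the test, with HIF1A and KDR well above background on 5 of 6 arrays at 5% O2. SOX2 was at -0.33 and passed without the low-signal array (adjusted p = 0.0269). POU5F1 was then at 0.07, NANOG at 0.51, HIF1A at 0.03, EPAS1 at -0.23 and KDR at -0.12. The camera adjusted p was 4.96e-23 for HIF targets, 2.51e-07 for metallothioneins, 1.72e-05 for cell cycle, 0.00018 for neuroectoderm, 0.00053 for Wnt, 0.0012 for respiratory chain, 0.00291 for glycolysis, 0.0061 for cholesterol synthesis, 0.0188 for endoderm and 0.0221 for neural crest genes. With an estimated correlation none held, with adjusted p = 0.0847 for HIF targets and adjusted p from 0.129 to 0.514 for the other lists. The HIF target list had 35 members higher, a median of 1.64 and an adjusted p = 0.0026 with an estimated correlation when the low-signal array was left out. Leaving it out also ended the endoderm and neural crest calls (adjusted p = 0.0618 and adjusted p = 0.0548) and made a call of the fibroblast list (adjusted p = 1.92e-05).

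For 5% against 21% O2 limma called 3774 of 24281 genes, 1664 higher and 2110 lower, with 1479 changed at least 2-fold. The count was 595 with only the arrays of both O2 levels. Leaving out the low-signal array gave 6631, of which 3623 were among the 3774. Without the other array of its group, 5 d at 5% O2 replicate 1, 16143 were called. The count was 2310 and 2311 without 12 h 5% O2 replicate 1 or 2, 2325 without 12 h 21% O2 replicate 1, 2347 without 24 h 21% O2 replicate 2 and 2484 without 5 d 21% O2 replicate 1, and it was 1203 with slide as a fixed block. Within slides the HIF target median was 1.55 and 1.41 at 12 h, 1.67 at 24 h and 1.90 at 5 d, the neuroectoderm median -0.91, -0.47, -0.74 and -1.13, and the metallothionein median 1.34, 1.52, 0.87 and -0.29. The glycolysis median was 0.81, 0.90, 0.19 and 0.58, and the fibroblast median -0.06, -0.28, 0.68 and 1.36. The cholesterol synthesis median was 0.77, 0.96, 0.81 and -0.19, and the endoderm median -2.03, -1.82, 0.10 and 0.15, so these went both ways. The respiratory chain median was 0.08, 0.29, -0.10 and -0.54, against the direction of the call at 12 h. The median was -0.22, -0.03, -0.31 and -0.54 for cell cycle, -0.70, -0.75, -0.16 and -0.17 for Wnt and -1.15, -0.74, -0.68 and -0.17 for neural crest genes.

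Between 1% and 5% O2, 27 of 36 HIF target genes were higher at 1% O2 (33 adjusted over the list alone, median 1.46), with CA12, a carbonic anhydrase gene, at 2.16 ± 0.20, NDRG1 at 2.28 ± 0.35 and CA9 at 1.90 ± 0.19, while VEGFA differed by 0.58 ± 0.38 and did not pass. VEGFA differed by 1.1 ± 0.20 and passed without the low-signal array (adjusted p = 0.000795). IL6 was higher by 3.15 ± 0.33 (limma adjusted p = 5.47e-05), CSF2 by 2.74 ± 0.56 and CSF3 by 2.5 ± 0.36, each on 6 of 6 arrays, with CSF2 and CSF3 well above background on 5 of 6 arrays at 5% O2. Of 23 fibroblast and matrix markers 15 were higher (19 adjusted over the list alone, median 1.20), with the fibrillin gene FBN1 at 1.65 ± 0.32 and the decorin gene DCN at 1.56 ± 0.37, or 1.00 without the low-signal array. Higher members numbered 8 of 19 in glycolysis (median 0.80), 10 of 22 in cholesterol synthesis (median 0.61, 1 lower), 9 of 23 in stress (median 0.40), 7 of 10 in metallothionein (median 0.76, 1 lower) and 5 of 21 in p53 target genes (median 0.45). The p53 targets included the cell cycle inhibitor gene CDKN1A at 1.46 ± 0.32 and the death receptor gene FAS at 1.33 ± 0.17 (5 of 6 arrays at 5% O2 well above background). Of 28 pluripotency markers 3 were lower and 1 higher (median -0.27), and ID4, an inhibitor of differentiation factors, fell by 1.79 ± 0.33. POU5F1 differed by -0.26 ± 0.20, NANOG by -0.19 ± 0.29, HIF1A by 0.19 ± 0.36, EPAS1 by 0.96 ± 0.46 and KDR by -0.30 ± 0.22, none past the test. SOX2 differed by 0.06 ± 0.25 and by -0.30 without the low-signal array (adjusted p = 0.042). POU5F1 then differed by -0.03, NANOG by -0.52, HIF1A by -0.35, EPAS1 by 0.27 and KDR by -0.46.

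The camera adjusted p for 1% against 5% O2 was 2.92e-24 for HIF targets, 2.21e-10 for fibroblast markers, 6.02e-07 for cholesterol synthesis, 2.07e-06 for metallothioneins, 9.21e-06 for glycolysis, 4.40e-05 for stress, 0.00504 for pluripotency and 0.00699 for p53 target genes. With an estimated correlation none held, with adjusted p = 0.0847 for HIF targets and adjusted p from 0.143 to 0.368 for the others, and HIF targets had an adjusted p = 0.00803 with an estimated correlation without the low-signal array. Leaving that array out ended the p53 call (adjusted p = 0.0872). The cell cycle list had 7 of 34 members lower, a median of -0.08 and an adjusted p = 0.0576 with it, and 20 lower, -0.35 and 8.52e-08 without it. Limma called 3422 of 24282 genes, 1739 higher and 1683 lower at 1% O2. With only the arrays of both O2 levels it called 215, 171 higher and 44 lower. Leaving out 5 d 5% O2 replicate 1 gave 15559, leaving out the low-signal array 7024, and slide as a fixed block 1724. The count was 2207 and 2231 without 12 h 5% O2 replicate 2 or 1, and 2257 without 12 h 1% O2 replicate 2. Within slides, at 12 h, 12 h, 24 h and 5 d, the last with the low-signal array, the median was 1.11, 1.02, 1.32 and 2.82 for HIF targets, 1.18, 1.05, 0.57 and 2.08 for fibroblast markers and 0.23, 0.35, 0.55 and 1.35 for glycolysis. It was 0.20, 0.17, 0.58 and 1.98 for cholesterol synthesis, 0.65, 0.54, 1.13 and 0.14 for metallothioneins, 0.20, 0.14, 0.64 and 1.55 for stress, 0.09, 0.01, 0.25 and 1.66 for p53 target and -0.37, -0.51, -0.29 and 0.25 for pluripotency genes.

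**Figure D3:**
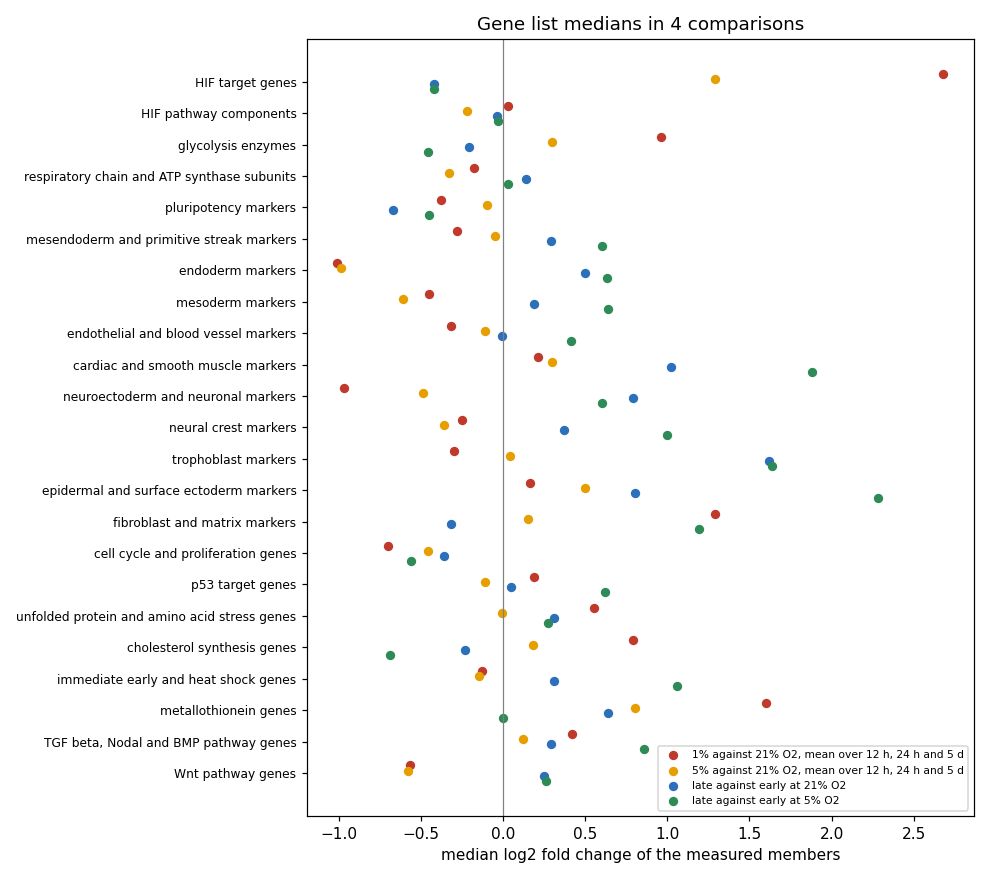
Points give the median log2 difference of the measured members of 23 gene lists, 1 row per list, in 4 comparisons shown by colour. HIF target genes lie at 2.68 for 1% and 1.29 for 5% against 21% O2, and trophoblast markers at 1.62 and 1.64 for late against early.

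The arrays at 21% O2 serve in both hypoxia comparisons, so their results are not independent. Of the genes called, 1241 were higher in both and 1686 lower in both, where 232.3 and 354.2 would be shared by independent lists. The differences correlated across genes at r = 0.69, where 20 simulations without effects gave 0.5 from the shared arrays alone. With the 21% O2 arrays divided between the comparisons, 1 array of each time to each, r was 0.53 and 0.65, and the covariance was 0.293 and 0.337 against 0.348 with shared arrays and 0.063 simulated.

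At each time 1% O2 was compared with 21% O2 to see when the change was present. Of 36 HIF target genes 32 rose at 12 h (median 2.57), 33 at 24 h (2.85) and 31 at 5 d (2.55). At 10 d, with 1 array on each side and the spread taken from the other groups, 25 rose (median 2.38). CSF2 rose by 6.71 ± 0.96 at 12 h (1 of 2 arrays at 21% O2 well above background) and by 6.85 ± 0.96 at 24 h, and ANKRD37 by 5.44 ± 0.41 and 5.79 ± 0.41. At 5 d CSF3 was at least 179-fold higher, SERPINB3, which encodes a protease inhibitor of squamous epithelia, at least 41.1-fold higher, and CXCL8 rose by 6.87 ± 0.96. At 10 d CSF2 was at least 614-fold higher, the receptor gene OSMR rose by 7.36 ± 0.84 and the matrix protease gene MMP3 by 7.26 ± 0.63. Among fibroblast and matrix markers 5 of 23 rose at 12 h (median 0.92), 5 at 24 h (0.90), 15 at 5 d (2.19) and 8 at 10 d (1.85).

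Among the falls at 1% O2, SIX6, an eye field gene, was at least 4.57-fold lower at 12 h. At 24 h ZNF594, a zinc finger gene, was at least 16-fold lower, TRMT61B at least 6.60-fold lower, and CYREN fell by 4.92 ± 0.34. At 5 d the fibrinogen genes FGG fell by 6.32 ± 2.06 and FGB fell by 5.69 ± 1.78 (1 of 2 arrays at 1% O2 well above background for each), and 9 of 21 endoderm markers fell (median -1.43). At 10 d FABP1, which encodes the liver fatty acid binding protein, was at least 289-fold lower and the apolipoprotein gene APOC3 at least 61.1-fold lower, and 11 of 21 endoderm markers (median -2.41) and 10 of 22 neuroectoderm markers (median -2.22) fell. At 10 d there was 1 array on each side, with the spread taken from other groups. FABP1 and APOC3 also differed widely between the 2 arrays at 0 h. SH3D21 fell by 6.69 ± 0.76 at 5 d, but 1 other probe of it moved in the opposite direction and passed the test. SH3D21 was well above background on 1 of 2 arrays at 21% O2.

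Limma called 2157 genes at 12 h, 901 higher and 1256 lower, 5245 at 24 h (2466 and 2779), 3995 at 5 d (2054 and 1941) and 5782 at 10 d (2349 and 3433). Without the low-signal array the counts were 6409, 10733, 10104 and 11097. With slide as a fixed block they were 1557 at 24 h and 1264 at 5 d, or 8459 and 6558 without the low-signal array too. No slide held both O2 levels at 24 h or 5 d, so the block rests on other groups there. With only the arrays compared 4474 genes were called at 12 h. Leaving out any 1 array of the 12 h groups gave 783 to 1136 genes. At 24 h the count was 3184 without 24 h 1% O2 replicate 1 and 2916 without 24 h 21% O2 replicate 2, and at 5 d it was 2200 without 5 d 1% O2 replicate 2 and 2012 without 5 d 21% O2 replicate 1. The median difference over all genes was -0.22 at 5 d and -0.18 at 10 d, so differences there stand against these shifts. The fit at 10 d assumes that the lone arrays vary like those of the other groups.

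At 5% against 21% O2 18 of 36 HIF target genes rose at 12 h (median 1.46), 14 at 24 h (1.63), 13 at 5 d (0.91), 17 at 10 d (1.88), where 21% O2 had 1 array, and 14 at 15 d (1.40), and 31 at 5 d (1.67) without the low-signal array. CSF2 rose by 5.66 ± 0.96 at 12 h (1 of 2 arrays at 21% O2 well above background), by 4.35 ± 0.96 at 24 h and by 4.73 ± 0.96 at 15 d, and was at least 76.2-fold higher at 10 d. At 10 d the cytokine genes CXCL8 and IL1B rose by 5.27 ± 1.17 and 4.99 ± 0.82, while HES5, a Notch-driven gene of neural progenitors, fell by 6.61 ± 0.63 and RAX fell by 6.08 ± 0.82. At 15 d the keratin gene KRT6B was at least 13.7-fold higher and C3AR1, a complement receptor gene, at least 102-fold lower. CGA, which encodes the alpha chain shared by chorionic gonadotropin and pituitary hormones, fell by 5.15 ± 0.81. At 10 d and at 15 d the arrays at 5% and 21% O2 shared no slide and no scan day. Oxygen therefore cannot be told apart from slide or scan day in the results of these times. Of 22 neuroectoderm markers 6 fell at 10 d (median -1.20) and 7 at 15 d (median -1.45). Fibroblast and matrix markers had 0 of 23 higher and 1 lower at 12 h (median -0.16) and 0 higher at 24 h (0.48), then 7 higher at 5 d (0.33), 7 at 10 d (1.79) and 3 at 15 d (1.16).

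At 12 h MGP, an inhibitor of calcification, was at least 7.97-fold lower and the fibrinogen gene FGA at least 13.5-fold lower, and at 24 h the desmosomal gene DSG1 was at least 3.88-fold lower. At 5 d, where 1 of the 2 arrays at 5% O2 was the low-signal array, CD86 rose by 7.64 ± 1.5 and LRRC2 by 7.15 ± 1.53, with group values of 5.84 ± 4.66 and 2.43 ± 5.44 (SD, n = 2) on the log2 scale. CABP7 rose by 7.14 ± 1.95. These differences were 4.34 for CD86, 3.31 for LRRC2 and 2.04 for CABP7 without the low-signal array, and CABP7 was then not called. SHISA2, which encodes an inhibitor of Wnt and FGF receptors, fell by 4.59 ± 0.58 (1 of 2 arrays at 5% O2 well above background). At 5 d 8 of 13 epidermal markers rose (median 2.74), and 7 did so (median 1.76) without the low-signal array.

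Limma called 1820 genes for 5% against 21% O2 at 12 h (566 higher and 1254 lower), 1205 at 24 h (577 and 628), 7081 at 5 d (3143 and 3938), 1469 at 10 d (816 and 653) and 815 at 15 d (469 and 346). Without the low-signal array the count at 5 d was 2206, of which 1503 were among the 7081, and the others were 5739, 6431, 6073 and 4389 in order of time. With only the arrays of the groups compared limma called 6717 at 12 h, 0 at 24 h (5659 at an unadjusted p under 0.05), 0 at 5 d (423) and 6383 at 15 d. At 10 d such a fit takes its spread only from the 10 d 5% O2 pair. That pair differed by less than spots of one array, so the count at 10 d cannot be read as a number of changed genes and is left out here. The arrays of 12 h at 5% O2 and of 15 d at 21% O2 were close too, with medians of 0.078 and 0.081 against 0.053 and 0.05 between spots. They enter the spread at 12 h and 15 d, whose counts may therefore be too high. With the 10 d 5% O2 arrays as 1 sample the count at 10 d was 504, and slide as a fixed block gave 47 at 24 h, 302 at 5 d, 56 at 10 d and 6 at 15 d. Without the low-signal array that block gave 5195 at 24 h and 717 at 15 d. Scan day as a fixed block gave 70 at 15 d, where the O2 levels shared no slide and no scan day. They shared none at 10 d either, so at both times the blocks rest on other groups. At 5 d quantile normalization called 2518 genes higher and 5037 lower. The median over all genes at 5 d was 0.13, or -0.19 with that normalization, while at 24 h it was -0.105. Leaving out any 1 array of the 12 h groups at 5% and 21% O2 gave 639 to 714 genes there, and leaving out either 10 d 5% O2 array 518 or 534. At 24 h it was 256 without 5% O2 replicate 1, and 479 and 217 without 21% O2 replicate 1 or 2. At 5 d it was 18133 without 5% O2 replicate 1, and 455 and 1767 without 21% O2 replicate 1 or 2. At 15 d it was 147 and 372 without 5% O2 replicate 1 or 2, and 85 and 89 without 21% O2 replicate 1 or 2.

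**Figure D4:**
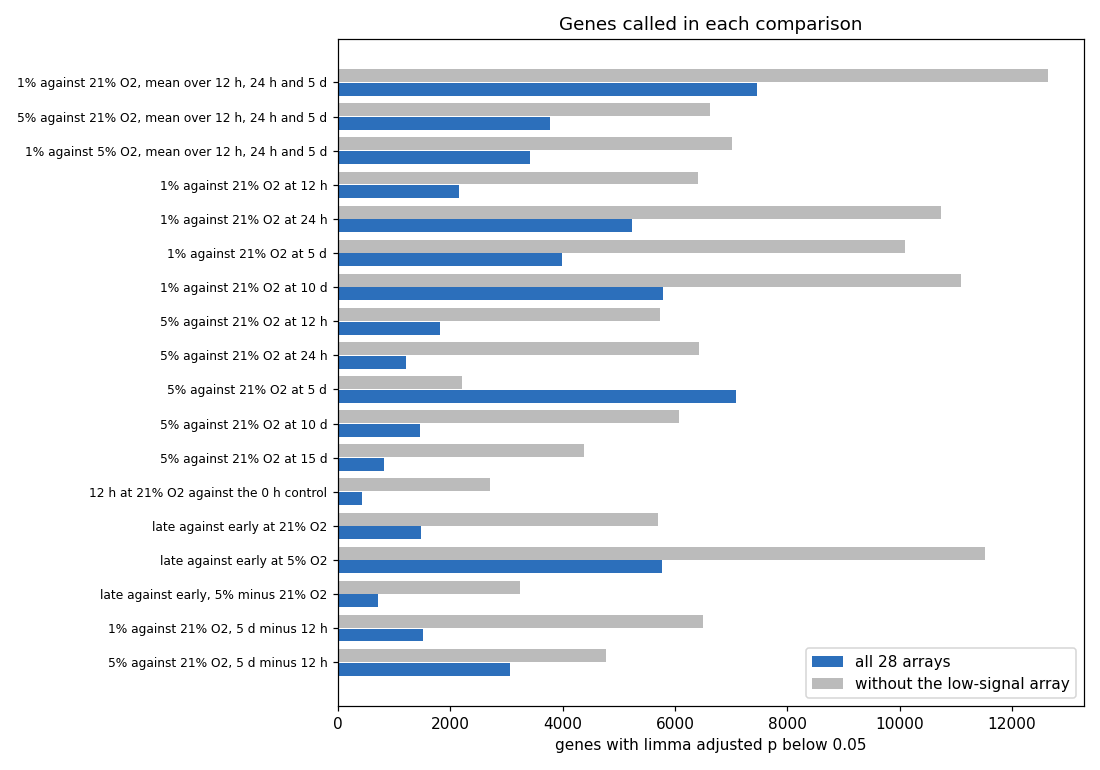
Bars start at 0 and give the number of genes called by limma in each comparison with all 28 arrays and without the low-signal array. At 5% against 21% O2 at 5 d the count was 7081 with that array and 2206 without it.

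Cells at 21% O2 after 12 h were compared with the 0 h control to see what changed without a change of oxygen. TP63, a regulator of epithelial stem cells, rose by 3.88 ± 0.48 (limma adjusted p = 0.00106), from -5.05 ± 0.27 to -1.17 ± 0.13 (SD, n = 2) on the log2 scale, and the immediate early gene FOS rose by 3.80 ± 0.44. MLC1 rose by 3.24 ± 0.52 (1 of 2 arrays at 0 h well above background). IL1RN was at least 3.48-fold lower and SEMG1 at least 2.97-fold lower at 12 h, and SERPINB3 fell by 2.78 ± 0.66 (1 of 2 arrays at 12 h well above background). Of 10 metallothionein genes 7 fell (9 adjusted over the list alone, median -1.68), and 2 of 36 HIF target genes rose (median 0.42). Limma called 424 genes, 360 higher and 64 lower. With only the arrays of these groups it called 0, and 5499 had an unadjusted p under 0.05. Without the low-signal array it called 2706, with slide as a fixed block 23, without control replicate 1 or 2 it called 62 and 171, and without 12 h 21% O2 replicate 1 or 2 it called 41 and 132.

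At 21% O2 the late arrays (1 at 10 d and 2 at 15 d) were compared with the 4 early arrays (12 h and 24 h) to describe change with time in culture. Of 21 trophoblast markers 11 rose and 1 fell (14 and 1 adjusted over the list alone, median 1.62). CGA rose by 6.97 ± 0.64 (1 of 4 early arrays well above background), the placental steroid enzyme gene HSD3B1 by 4.47 ± 0.65 (2 of 4 early arrays), VGLL1 by 3.71 ± 0.32 and TP63 by 3.62 ± 0.38, each higher on 3 of 3 late arrays than on any early array. VIT was at least 26.3-fold higher and MAB21L4 at least 15.7-fold higher. Of 22 neuroectoderm markers 9 rose and 0 fell (median 0.79), with HES5 at 4.22 ± 0.41 and LHX2 at 2.85 ± 0.39, and NEUROD1, a neuronal differentiation gene, at least 6.78-fold higher. Of 18 cardiac and smooth muscle markers 5 rose (median 1.02), with the myosin gene MYH6 at 3.36 ± 0.36. Epidermal markers had 2 of 13 higher (median 0.80), 1 of them SFN at 1.79 ± 0.27, metallothioneins 4 of 10 higher (median 0.64) and stress genes 3 of 23 higher (median 0.31).

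Of 28 pluripotency markers 9 fell late at 21% O2 and 2 rose (13 and 2 adjusted over the list alone, median -0.67), with PRDM14 at -1.97 ± 0.35, the growth factor gene GDF3 at -1.48 ± 0.25 and LEFTY2 at 1.57 ± 0.37. POU5F1 differed by -0.84 ± 0.27, NANOG by -1.06 ± 0.39 and SOX2 by -1.08 ± 0.34, none past the test with all arrays. Each passed without the low-signal array (adjusted p = 0.00254, adjusted p = 0.00962 and adjusted p = 4.82e-05). HESX1, a forebrain and pituitary gene, fell by 2.89 ± 0.29, FGF5, a gene of primed pluripotent cells, was at least 3.67-fold lower, and MMP1 fell by 2.21 ± 0.30. Of 36 HIF target genes 5 fell (8 adjusted over the list alone, median -0.42), such as the mitophagy receptor gene BNIP3 at -1.75 ± 0.43. Of 34 cell cycle genes 3 fell (median -0.36), such as BUB1 at -1.03 ± 0.21, of 23 fibroblast markers 3 fell (median -0.32) and 1 of 22 cholesterol synthesis genes fell (median -0.23). Endothelial markers had 1 of 21 higher and 3 lower (median -0.01), with the vessel gene VWF at -1.94 ± 0.45. VEGFA, CA9, HIF1A, EPAS1 and KDR differed by -0.39 ± 0.52, -0.13 ± 0.26, -0.23 ± 0.49, 0.89 ± 0.62 and -0.40 ± 0.30, none past the test. EPAS1 passed without the low-signal array (adjusted p = 0.00521).

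The camera adjusted p for late against early at 21% O2 was 3.50e-11 for trophoblast, 1.97e-08 for pluripotency, 1.24e-06 for neuroectoderm, 1.62e-06 for HIF target, 1.64e-05 for metallothionein, 3.70e-05 for cell cycle, 8.93e-05 for cardiac, 0.00112 for epidermal, 0.0205 for cholesterol synthesis, 0.0206 for stress and 0.0607 for fibroblast genes. The trophoblast call held with an adjusted p = 0.0101 with an estimated correlation, and the other calls did not, with adjusted p from 0.0565 for neuroectoderm to 0.545 for cholesterol synthesis genes. Limma called 1482 of 24278 genes, 908 higher and 574 lower late. The count without the low-signal array was 5700 and 127 with slide as a fixed block, or 2331 with both changes. It was 8263 with only the arrays compared, among them the closely similar 15 d pair, so it may be too high. The count was 980 and 947 without 12 h 21% O2 replicate 1 or 2, 837 without 24 h 21% O2 replicate 1, and 895 and 839 without 15 d 21% O2 replicate 1 or 2.

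At 5% O2 the 4 late arrays were compared in the same way with the 4 early ones. Of 21 trophoblast markers 14 rose and 1 fell (14 and 1 adjusted over the list alone, median 1.64), with KRT23 at 5.35 ± 0.62 (3 of 4 early arrays well above background), TP63 at 5.47 ± 0.34 and VGLL1 at 4.31 ± 0.28 (1 of 4). Of 13 epidermal markers 9 rose (10 adjusted over the list alone, median 2.28), with the basal keratin gene KRT5 at 5.28 ± 0.92 (2 of 4 early arrays) and KRT17 at 4.37 ± 0.47. XAGE2 rose by 7.30 ± 0.51 (2 of 4 early arrays), SLPI, which encodes a secreted protease inhibitor, by 5.70 ± 0.87 and GABRP by 5.37 ± 0.43, while VIT was at least 26.8-fold and ODAPH at least 25.3-fold higher. Of 18 cardiac and smooth muscle markers 12 rose and 1 fell (median 1.88), with the atrial myosin gene MYL7 at 2.91 ± 0.38. Of 23 fibroblast and matrix markers 11 rose (14 adjusted over the list alone, median 1.19), with the collagen gene COL3A1 at 1.83 ± 0.32. Mesoderm markers had 7 of 20 higher (median 0.64), immediate early genes 8 of 20 (median 1.06), with FOS at 3.99 ± 0.31, TGF beta pathway genes 10 of 24 (median 0.86) and p53 targets 8 of 21 (median 0.62).

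Of 28 pluripotency markers 13 fell and 4 rose late at 5% O2 (median -0.45): SOX2 fell by 1.97 ± 0.31, whereas LEFTY2 rose by 4.02 ± 0.33 and NODAL by 3.11 ± 0.32 (1 of 4 early arrays well above background). POU5F1 differed by -0.26 ± 0.24 and NANOG by 0.10 ± 0.35, neither past the test. Of 22 neuroectoderm markers 6 rose and 2 fell (median 0.60, camera adjusted p = 0.357). The neural genes NPTX1 and SOX21 fell by 4.10 ± 0.25 and 3.16 ± 0.28, HESX1 by 3.49 ± 0.26 and the forebrain gene OTX2 by 2.92 ± 0.33. Of 34 cell cycle genes 15 fell (median -0.56), with the mitotic kinase gene PLK1 at -1.52 ± 0.22. Of 22 cholesterol synthesis genes 10 fell (12 adjusted over the list alone, median -0.69), with MSMO1 at -2.17 ± 0.33. HIF target genes had 9 of 36 lower and 2 higher (median -0.42), with ANKRD37 at -1.87 ± 0.29 and CA9 at 1.26 ± 0.23, and glycolysis enzymes had 2 of 19 lower (median -0.46). EPAS1, which encodes HIF-2 alpha, rose by 1.88 ± 0.56, while VEGFA, HIF1A and KDR differed by -1.02 ± 0.46, 0.07 ± 0.44 and 0.57 ± 0.27, none past the test. VEGFA passed without the low-signal array (adjusted p = 0.00166). The liver-type genes TTR and FOXA1 rose by 2.89 ± 0.86 and 1.98 ± 0.48 (FOXA1 on 2 of 4 early arrays well above background), but with slide as a fixed block they differed by -0.57 and -0.28. Endoderm markers had 3 of 21 higher and 3 lower, with a median of 0.63 and a camera test in the downward direction (adjusted p = 0.892).

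The camera adjusted p for late against early at 5% O2 was 8.67e-08 for trophoblast, 2.51e-07 for cell cycle, 3.05e-07 for epidermal, 7.38e-06 for cholesterol synthesis, 4.40e-05 for cardiac, 6.46e-05 for fibroblast, 0.000374 for TGF beta, 0.000787 for immediate early, 0.0015 for HIF target, 0.00221 for mesoderm and for pluripotency, 0.00989 for p53 target and 0.02 for glycolysis genes. The trophoblast call held with an adjusted p = 0.0307 with an estimated correlation, or 0.0688 with an estimated correlation without the low-signal array, and the other calls did not hold, with adjusted p from 0.0565 for epidermal to 0.545 for HIF target genes. Over the 5 main comparisons 51 list tests were called, 2 of them with an estimated correlation. Limma called 5777 of 24281 genes, 3658 higher and 2119 lower late, and 11523 without the low-signal array. The count was 538 with slide as a fixed block, or 5181 with that block and without the low-signal array. It was 11312 with only the arrays compared. The median over all genes was 0.11.

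Tests of differences asked whether an effect differed between O2 levels or times. The late change differed between 5% and 21% O2 for 707 genes, 503 with a more positive change at 5% O2 and 204 with a more negative one. KRT5 differed by 5.78 ± 1.38 (limma adjusted p = 0.0343) and FOS by 3.67 ± 0.47, and HES5 by -4.22 ± 0.54 and CGA by -4.18 ± 0.86. KRT5 was well above background on 6 of 8 arrays at 5% O2 and 7 of 7 at 21% O2, and CGA on 5 of 8 and 4 of 7. KRT5 did not pass with the 10 d 5% O2 arrays as 1 sample (adjusted p = 0.0802). At 15 d CGA was at 3.08 ± 0.01 at 21% O2 and -2.06 ± 0.24 at 5% O2 (SD, n = 2, log2). In the epidermal list 3 of 13 members differed upward and in the fibroblast list 3 of 23 (medians 1.57 and 1.34). The count was 3246 without the low-signal array, 390 with the 10 d 5% O2 arrays as 1 sample, 3 with slide as a fixed block and 4511 with only the arrays compared. It was 405 and 403 without 12 h 5% O2 replicate 1 or 2, 427 without 12 h 21% O2 replicate 2, 410 without 24 h 21% O2 replicate 2, 388 and 396 without 10 d 5% O2 replicate 1 or 2, and 392 and 385 without 15 d 21% O2 replicate 1 or 2. Quantile normalization gave 247 upward and 161 downward, normexp with quantile normalization 249 and 198, and the series matrix 189 and 147. With slide as a fixed block and without the low-signal array 1167 genes were called.

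The effect of 1% against 21% O2 differed between 5 d and 12 h for 1516 genes, 835 upward and 681 downward. SERPINB3 differed by 7.23 ± 0.93 (limma adjusted p = 0.00053, well above background on 3 of 4 arrays at 1% O2 and 1 of 4 at 21% O2) and LEFTY2 by 5.61 ± 0.66, the latter at 1.34 ± 0.07 at 5 d in 1% O2 and -4.27 ± 0.01 in 21% O2. MADCAM1, a vascular adhesion gene, differed by -5.51 ± 0.43. The effect of 5% against 21% O2 differed between these times for 3063 genes, 1803 upward and 1260 downward, with MADCAM1 at -5.05 ± 0.43 and GNB5 at -4.77 ± 0.45 (3 of 4 arrays at 5% O2 well above background). The same 21% O2 arrays stand in both tests. Without the low-signal array the counts were 6498 and 4774, with 2578 of the 3063 among the latter, and with slide as a fixed block 190 and 950. With only the arrays of the groups compared limma called 3749 for 1% O2 and 0 for 5% O2, where 2641 had an unadjusted p under 0.05. For 5% O2, leaving out 1 array of the groups compared gave 952 to 16917, the highest without 5 d 5% O2 replicate 1, and the median over all genes was 0.21. For 1% O2 leaving out 1 such array gave 648 to 1464, and the median over all genes was -0.13.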

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

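The tests of 5 d at 5% O2 and those of slide and of a lower share of the main cell type for the trophoblast and epidermal lists were chosen after the results were seen. So was leaving out the low-signal array in every comparison. Only for comparisons that hold its group had leaving it out been planned, as for each array of the groups compared.

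The late change at 5% O2 differed from that at 21% O2 for 707 genes by a test of the difference itself. KRT5 (5.78 ± 1.38), MKX (3.78 ± 0.70) and FOS (3.67 ± 0.47) had a more positive late change at 5% O2, and HES5 (-4.22 ± 0.54), CGA (-4.18 ± 0.86) and RAX (-3.82 ± 0.71) a more negative one, with 8 arrays at 5% O2 and 7 at 21% O2. MKX was well above background on 5 of 8 and 5 of 7 of these and KRT5 on 6 of 8 and 7 of 7. With 23905 genes without missing values 710 were called, and 5 of 100 splits of the arrays gave as many, the highest other split 2152, so these splits could not exclude chance. The others with as many exchanged the O2 labels of most early arrays, which points to a structure of the samples by early oxygen level. Such an exchange puts the oxygen effects of both times into the count, so they do not show that chance gave it. With slide as a fixed block 3 genes were called, or 1167 with that block and without the low-signal array.

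The effect of 1% against 21% O2 differed between 5 d and 12 h for 1516 genes, with 4 arrays on each side. The difference was positive for SERPINB3 (7.23 ± 0.93), SERPINB4 (7.12 ± 1.07) and LEFTY2 (5.61 ± 0.66) and negative for SH3D21 (-7.33 ± 0.98), MADCAM1 (-5.51 ± 0.43) and MIR7-3HG (-5.16 ± 1.09). For 5% against 21% O2 the effect differed for 3063 genes, with CD86 (8.40 ± 2.13), LRRC2 (7.73 ± 2.16), FLG (6.40 ± 1.64), SH3D21 (-6.47 ± 0.98), MADCAM1 (-5.05 ± 0.43) and GNB5 (-4.77 ± 0.45). SH3D21 and MADCAM1 appear in both, and both tests use the same arrays at 21% O2. MADCAM1 was at -2.12 at 12 h and -0.03 at 5 d in 21% O2, against 0.14 and -3.28 in 1% O2. SERPINB4 was well above background on 2 of 4 arrays at 1% O2 and 0 of 4 at 21% O2, and FLG on 0 of 4 at 5% O2 and 1 of 4 at 21% O2, so their fitted values rest on dim spots. The differences without the low-signal array were 5.1 ± 1.51 for CD86, 3.89 ± 1.08 for LRRC2 and 4.88 ± 1.68 for FLG, which was then not called (adjusted p = 0.0539). Another probe of SH3D21 moved in the opposite direction and passed at 5 d for both 1% and 5% against 21% O2.

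Splits of the arrays into groups of the same sizes were tried for the main comparisons on the same 23905 genes. For 1% against 21% O2 the real count of 7458 was reached by 1 of 100 splits, the real one, with a highest other of 4118. For 1% against 5% O2 it was 3444, reached by 1 of 100, with a highest other of 2979. Both highest others exchanged the O2 labels of the 12 h and 24 h arrays. For 5% against 21% O2 it was 3784, reached by 2 of 100, and the other, with 3814, exchanged the low-signal array with an array at 21% O2. For late against early it was 1417 at 21% O2 and 5352 at 5% O2, each reached by 1 of 35 splits, with highest others of 270 and 46. These splits argued against chance for the 5 comparisons but did not exclude it, since for 5% against 21% O2 another split called more genes. Late and early arrays of the same O2 level shared no slide, so their splits cannot separate time from slide.

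More genes were called for 5% against 21% O2 at 5 d (7081) than at any other time. A change of the cells at that time common to both arrays was examined in fits without the low-signal array. These had 1 array at 5% O2 and 2 at 21% O2 at each of 12 h, 24 h, 5 d and 15 d. The count was then 2324 at 5 d in all 8 fits, 3879 or 3882 at 12 h, 3173 or 6768 at 24 h and 2319 or 3607 at 15 d. Without the low-signal array 5 d was thus not the time with the highest count. Since 1 array cannot show what both share, a change common to both stays open, as does one on the low-signal array alone. A wrong label alone would leave a correlation near that of other arrays, but the highest of this array was 0.683, below the lowest median of 0.912 of the others, though whether its label is right cannot be read from an array this dim. Little labelled sample RNA may explain the count, since the spike-in level minus the 75th percentile was 8.75, above 4.28, the highest of the other arrays. Whether little RNA was put on or it was degraded was not tested.

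The cytokine genes CSF2, CSF3, IL6, CXCL8, IL1A and IL1B were higher at 1% than at 21% O2, with a median of 5.55 over the mean of 12 h, 24 h and 5 d. Slide was argued against at 12 h and 10 d only. The lowest median within the 3 slides that held both O2 levels, 2 of 12 h and 1 of 10 d, was 3.5. At 10 d, which is not in that mean, IL6 differed by 2.43. No slide held both levels at 24 h or 5 d, so slide stays open there. More cells of fibroblast type at 1% O2 remain open, since the fibroblast and matrix list had a median of 1.29 with 17 of 23 members higher, and the cells grew on matrix and in medium from fibroblasts. That median lies far below the cytokines' 5.55. At 5% O2 after 12 h CSF2 rose by 5.66 ± 0.96 (1 of 2 arrays at 21% O2 well above background). The fibroblast list then had medians of -0.06 and -0.28 within slides. However, 22 of 23 fibroblast markers were well above background on both 0 h arrays, which could hide a small share of such cells. These values therefore cannot decide between such cells and a response of the same cells. A response to hypoxia itself stays among the open explanations.

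The trophoblast list had medians of 1.62 and 1.64 late against early at 21% and 5% O2, with 11 and 14 of 21 members called higher, and the epidermal list 0.80 and 2.28, with 2 and 9 of 13. With slide as a fixed block and without the low-signal array these medians were 2.14 and 1.39, and 1.81 and 2.38. The lowest ratio of these to the medians without the block was 0.85. No slide held both late and early arrays at the same O2 level, so the block rests on other groups. It therefore cannot decide whether slide was the cause. A lower share of the main cell type would raise the markers of all other types, and at 21% O2 the lowest median of the 6 other lists was -0.32, that of fibroblast markers. Endothelial markers had quartiles of -0.68 and 0.40, below the 0.68 and 3.08 of trophoblast markers. Of the fibroblast markers 22 of 23 and of the endothelial markers 16 of 21 were well above background at 0 h, which could hide a small share, so a lower share stays open at 21% O2. At 5% O2 the lowest median was 0.41, and it stays open there too, as does differentiation toward these types at both levels.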

How the results depend on the processing

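The tests with the low-signal array left out of every comparison, alone or with slide as a fixed block, were chosen after the data were seen. So were those with scan day as a block and with the 10 d 5% O2 arrays as 1 sample. Leaving the low-signal array out alone had been planned only for comparisons that hold its group.

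Most alternatives gave 559 results of a named gene in a comparison, and the series matrix 513. Of these 554 kept their direction and side of the threshold with slide as a random block, 542 with replicate number as a block, 541 without the low-signal array, 514 with the 10 d pair as 1 sample, 513 without a filter, 509 with normexp and quantile normalization together, 509 with the mean of probes, 493 with quantile normalization, 492 with scan day, 477 without the low-signal array with slide fixed, 442 with the series matrix and 321 with slide fixed, where 232 lost their call. Leaving out each array of the groups compared in turn gave 5266 such results over all arrays, of which 4544 kept both and 687 lost their call. Of the list tests 92 kept their side with slide fixed and 94 without the low-signal array. The number of lists called lay between 47 and 56 when 1 array was left out so.

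With slide as a fixed block these genes reversed late at 5% O2: TTR (-0.57) and FOXA1 (-0.28), or -0.77 and -0.36 without the low-signal array too. With the mean of probes CREBBP reversed for 5% against 21% O2 (-0.00), SNAI2 for 1% against 5% O2 (-0.10) and SH3D21 for 5% against 21% O2 at 5 d (0.33). SOX2 for 1% against 5% O2 was -0.30 without the low-signal array and 0.41 without the other array of its group. The cause was not tested for any of these.

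Counts of called genes follow by alternative, where they moved over 1.5 times. Those over times are over the mean of 12 h, 24 h and 5 d. Slide as a fixed block gave 4483 for 1% against 21% O2 over times, 1557 at 24 h, 1264 at 5 d and 190 for 5 d minus 12 h, 1724 for 1% against 5% O2, and for 5% against 21% O2 1203 over times, 47 at 24 h, 302 at 5 d, 56 at 10 d, 6 at 15 d and 950 for 5 d minus 12 h. It gave 23 for 12 h against 0 h, 127 late at 21% O2, 538 late at 5% O2 and 3 for their difference. Without the low-signal array the same block gave 2404, 2331, 5181 and 1167 for these, so the low counts depended on keeping that array. Why the block and that array act together was not tested.

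The low-signal array left out gave 12644 for 1% against 21% O2 over times, 6409, 10733, 10104 and 11097 at 12 h, 24 h, 5 d and 10 d and 6498 for 5 d minus 12 h, 7024 for 1% against 5% O2, and for 5% against 21% O2 6631 over times, 5739, 6431, 2206, 6073 and 4389 at 12 h to 15 d and 4774 for 5 d minus 12 h. It gave 2706 for 12 h against 0 h, 5700 and 11523 late at 21% and 5% O2 and 3246 for their difference. This array enters the spread of every comparison with all arrays. With slide fixed as well the counts were 7481, 8459, 6558 and 12284 for 1% against 21% O2 at 12 h, 24 h, 5 d and 10 d, 4981 for 5 d minus 12 h and 5174 for 1% against 5% O2. For 5% against 21% O2 they were 7008 over times, 6740, 5195, 3545 and 3321 at 12 h, 24 h, 5 d and 10 d and 6348 for 5 d minus 12 h, and 2404 for 12 h against 0 h, 2331 late at 21% O2 and 1167 for the difference.

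With only the arrays of the groups compared, limma called 11324 for 1% against 21% O2 over times, 4474 at 12 h and 3749 for 5 d minus 12 h, 215 for 1% against 5% O2 (171 higher, 44 lower), and for 5% against 21% O2 595 over times, 6717 at 12 h, 16500 at 10 d and 6383 at 15 d. It called 8263 late at 21% O2, 11312 late at 5% O2 and 4511 for the difference. It called 0 for 5% against 21% O2 at 24 h (5659 at an unadjusted p under 0.05), 0 at 5 d (423), 0 for its 5 d minus 12 h (2641) and 0 for 12 h against 0 h (5499). At 10 d 1% against 21% O2 could not be fitted so, with 1 array a side. For 5% against 21% O2 at 10 d the spread came only from the 10 d 5% O2 pair. That pair differed by less than spots of one array. The count given for 10 d therefore cannot be read as a number of changed genes, and no result rests on it. Similar pairs of 10 d or 12 h at 5% O2 or 15 d at 21% O2 enter the spread behind 6717, 6383, 8263, 11312 and 4511. These counts may therefore be too high.

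Quantile normalization gave for 5% against 21% O2 1133 at 12 h, 744 at 24 h, 536 at 15 d and 1849 for 5 d minus 12 h, 239 for 12 h against 0 h and 408 for the late difference. Normexp with quantile normalization gave 1162 for 5% against 21% O2 at 12 h, 225 for 12 h against 0 h (155 higher, 70 lower) and 447 for the late difference. The series matrix gave for 5% against 21% O2 1040 at 12 h, 652 at 24 h, 510 at 15 d and 1844 for 5 d minus 12 h, 169 for 12 h against 0 h, 336 for the late difference and 1432 for 1% against 21% O2 at 12 h. Normexp with quantile normalization split 5 d minus 12 h at 5% O2 into 1041 higher and 1245 lower. No filter gave 538 for 5% against 21% O2 at 15 d and 272 for 12 h against 0 h. Scan day gave for 5% against 21% O2 1669 at 5 d, 909 at 10 d, 70 at 15 d and 1762 for 5 d minus 12 h, 908 late at 21% O2 and 304 for the difference. The 10 d pair as 1 sample gave 504 for 5% against 21% O2 at 10 d and 390 for the difference, and within 1.5 times 6935, 3072 and 2890 for the comparisons over times and 1234 and 4215 late at 21% and 5% O2. The cause was not tested for these.

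Leaving out 1 array of the groups compared gave 6100 to 7107 for 1% against 21% O2 over times, 783 to 1136 at 12 h, 2916 to 4287 at 24 h, 2012 to 3113 at 5 d and 648 to 1464 for 5 d minus 12 h. It gave 2207 to 15559 for 1% against 5% O2, and for 5% against 21% O2 2310 to 16143 over times, 639 to 714 at 12 h, 217 to 1296 at 24 h, 455 to 18133 at 5 d, 518 to 534 at 10 d, 85 to 372 at 15 d and 952 to 16917 for 5 d minus 12 h. It gave 41 to 171 for 12 h against 0 h, 837 to 1156 late at 21% O2, 4235 to 5194 late at 5% O2 and 385 to 620 for the difference. The lone arrays at 10 d could not be left out, and a lone array left in a group is assumed to vary like other groups. The highest counts came without 5 d 5% O2 replicate 1, which leaves the low-signal array alone in its group and so out of the spread. Signal over background limits genes near the floor, with 52.2% of probes well above background on the low-signal array.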

Other observations

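No tests were added in this part, and its values were looked at after the results were seen.

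Liver-type genes differed widely between the 2 arrays of cells at 0 h: FABP1 was at -0.36 ± 3.63, FGG at -1.33 ± 4.82, FGB at -1.56 ± 3.29 and APOC3 at -4.09 ± 4.27 (SD, n = 2, log2 relative to the 75th percentile). FABP1 was at 4.0 ± 0.07 at 15 d in 21% O2. MT1X, a metallothionein gene, was at 5.10 ± 0.29 at 0 h, 3.41 ± 0.02 at 12 h in 21% O2 and 5.55 at 12 h in 1% O2. Its difference between these O2 levels at 12 h was thus mostly a fall at 21% O2.

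Replicate arrays differed by a median of 0.148 to 0.328 on the log2 scale in most groups at probes with several spots. Those of 10 d at 5% O2 differed by 0.037, of 12 h at 5% O2 by 0.078 and of 15 d at 21% O2 by 0.081, against 0.054, 0.053 and 0.05 between spots of one array. Replicate 1 of 5 d at 21% O2 had 448 spots marked as non-uniform, where the next array had 26, and 114 saturated probes.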
